A study of Mus musculus with 8 samples.

How the data were processed

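The samples were brown adipose tissue (brown fat) and quadriceps muscle of C57BL/6J mice kept at room temperature or placed at 4 °C for 4 h. Each of the 4 combinations of tissue and temperature was represented by 2 arrays, which gives 8 arrays. Per the labels' protocols, the cold-exposed mice had free access to food overnight and were then housed without food or bedding during the exposure. Whether the mice at room temperature were handled in the same way is not stated. Total RNA was extracted with TRIzol, amplified and labelled with biotin, and hybridised to an Illumina bead array with 1 colour, per the labels' protocols.

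The first table holds, per the file headers, 1 signal for each of 24607 probes on each array, which is an intensity on a linear scale. These deposited intensity values had no background subtracted and no scaling between arrays, as judged from their lowest values and from medians that differ between arrays (87.3 to 98.1). The same table has a column headed as a detection p-value for each array. The deposited detection score rises with the signal and reaches 1 for the brightest probes, so it was read as 1 minus a detection p-value. The second table holds the authors' processed intensity values on a linear scale. Every array in it has the same minimum and maximum and 32.8% of all values lie below 0. It was therefore read as background subtracted and quantile normalized, and its rank order within each array was that of the first table (Spearman's rho of at least 0.99998). Its array medians lay between 14.91 and 15.05. The software that summarised the beads, the background method and the normalization method of the authors are not given in the sources used here.

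All computations were done in R 4.3.3 with limma 3.58.1. The mean and spread of the negative controls were inferred from the detection p-values. Signals were corrected with the normexp model, an offset of 16 was added, and values were quantile normalized over the 8 arrays and put on the log2 scale. A probe was tested if its detection p was under 0.05 on both arrays of at least 1 group, which 11946 probes met. Gene names came from the platform annotation supplied with the series. In it 20980 probes carry 1 gene symbol, 1 carries several and 3626 carry none, and 20964 of the 20980 were matched by gene identifier to a table of mouse RefSeq genes (assembly GRCm38.p6) used for names alone. For a gene with several tested probes, the probe with the highest mean was used, and a probe with no gene name stood for itself. This left 9963 rows, called genes here, of which 8561 have a name. Positions in the genome are not given, since no source names the build behind the array.

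A linear model with 4 group means was fitted to all 8 arrays with lmFit and eBayes, so that the groups share 1 estimate of spread with 4 residual degrees of freedom, to which the moderation added 3.07. Contrasts were the cold effect in brown fat, the cold effect in muscle, the difference between these effects, and the tissue difference at each temperature. P-values were adjusted with the Benjamini-Hochberg method over the 9963 genes, and an adjusted p under 0.05 is called past the threshold. Errors are standard errors (SE) of the log2 fold change unless marked as SD, and intervals are at the 95% level. With 2 arrays per group, the number of arrays limits the precision. The labels do not say that the replicates come from separate mice, nor whether brown fat and muscle arrays share mice, so p-values measure the spread between these samples, which may be technical in part. Where a gene was not above background on either array of the dimmer group, its fold is given as a bound, from the brighter group's mean and, per array of the dimmer group, the higher of the lowest signal of a detected probe and the gene's own.

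Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for named genes were fixed. The text names up to 10 genes with the largest change in each direction for both cold effects and for the tissue difference at room temperature. These had to have a name, be past the threshold, have group values that do not overlap, and be detected on both arrays of the brighter group. It further names 5 genes in each direction for the difference between cold effects, Zbtb16 throughout, up to 10 genes past the threshold in both tissues by the smaller change, and up to 4 members of each list that passed or up to 2 that did not. Some genes belong to more than 1 list, such as Foxo1, Cdkn1a, Klf15, Nr4a1, Per1 and Tek, so list results are not independent of each other. Lists were tested with camera (preset correlation between genes of 0.01) and fry, adjusted over the 31 lists within a contrast. Camera compares a list with all other genes. It was also run with the correlation estimated for each list. That form also rests on the 4 residual degrees of freedom, so a call lost there need not reflect correlation between genes. Fry tests whether a list's genes move on balance in 1 direction, and its mixed form whether they change in either direction; neither compares the list with other genes.

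The fit and camera were tested on simulated data. Normally distributed log2 values of the 9963 genes were drawn with the real tissue means in 20 simulations. Each gene had 1 spread, taken from the fit, in all groups. In each simulation 200 genes were changed in 1 comparison. For the cold effect in brown fat, 74.2% of genes changed by 1 log2 unit and 94.9% of those changed by 2 were recovered, with 7.6 false calls on average. For the cold effect in muscle these values were 72.8%, 94.6% and 7.35. A list of 30 genes raised by 1 log2 unit was called in 20 of 20 simulations in each tissue, and an unchanged list in 0. Genes were drawn independently and lists at random, so false calls of lists with correlated genes were not tested. Estimated correlations in the real lists were, for example, 0.952 for adipocyte markers and 0.729 for the interferon response.

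The alternatives were no background correction, an offset of 50, median scaling, quantile normalization within each tissue, the authors' processed values, no filter, a detection p under 0.01 on all 8 arrays, all probes, a fit on the compared groups alone, a variance trend with robust moderation, a minimum fold of 1.5, the replicate number as a block, and leaving out each array. A further 2 were chosen after seeing the data. The first left out the 2 arrays that carry the most signal of the other tissue, or lack signal the others carry. The second left out genes at least 2-fold higher in the other tissue. Without the 2 arrays each cold group has 1 array. The spread then comes from the room-temperature arrays alone, so counts and p-values of that setting are weak support. Camera with an estimated correlation rests on still fewer degrees of freedom there and cannot weigh lists. A block for chip or scan was not run, because the sources used here give neither. For muscle in the cold, titles and descriptions give opposite replicate numbers, and the titles' numbers are used.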

Results

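Gene expression was measured on 8 bead arrays, 2 for each combination of tissue (brown fat or quadriceps muscle) and temperature (room temperature or 4 °C for 4 h). Brown fat is the tissue that produces heat by uncoupled respiration, and the series title concerns Zbtb16, a zinc finger transcription factor, in the energy metabolism of brown adipocytes. Between 10468 and 11280 of the 24607 probes were above background on each array. Replicates correlated across the 9963 tested genes at 0.993 for brown fat and 0.9959 for muscle at room temperature, and at 0.977 and 0.9818 in the cold. The first principal component, with 85.6% of the variance, separated the tissues, and the next, with 6.35%, separated cold from room temperature within each tissue. All fold changes below compare means of 2 arrays per group (n = 2).

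Zbtb16 was higher in the cold in both tissues. In brown fat it rose from a mean log2 intensity of 5.99 ± 0.33 to 8.25 ± 0.15 (SD, n = 2), a 4.78-fold rise (log2 fold change 2.26, SE 0.17, adjusted p = 0.00117). In muscle the rise was 4.26-fold (2.09, SE 0.17, adjusted p = 0.00314). On single arrays it read 6.23 and 5.76 in brown fat at room temperature against 8.35 and 8.15 in the cold, and 6.72 and 6.58 against 8.80 and 8.68 in muscle. The effects differed between tissues by 0.17 (interval -0.40 to 0.74, adjusted p = 0.705). At room temperature Zbtb16 was lower in brown fat than in muscle by a log2 difference of -0.66 (SE 0.17, adjusted p = 0.0114), and in the cold by -0.49 (adjusted p = 0.0377). Both cold effects stayed past the threshold under every alternative in which the gene was tested. A detection p under 0.01 on all 8 arrays removed it. Over the alternatives the log2 fold change ran from 1.51 to 2.49 in brown fat and from 1.51 to 2.16 in muscle. In brown fat at room temperature replicate 2 read 5.76, close to the lowest detected signal of 5.645. The size of the brown fat rise is therefore uncertain. The tissue difference at room temperature lost its call with median scaling (adjusted p = 0.0535) and when brown fat replicate 2 (0.0534) or muscle replicate 1 (0.0675) at room temperature was left out, and the difference in the cold did so under several alternatives (adjusted p from 0.0146 to 0.156 over those run).

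**Figure D1:**
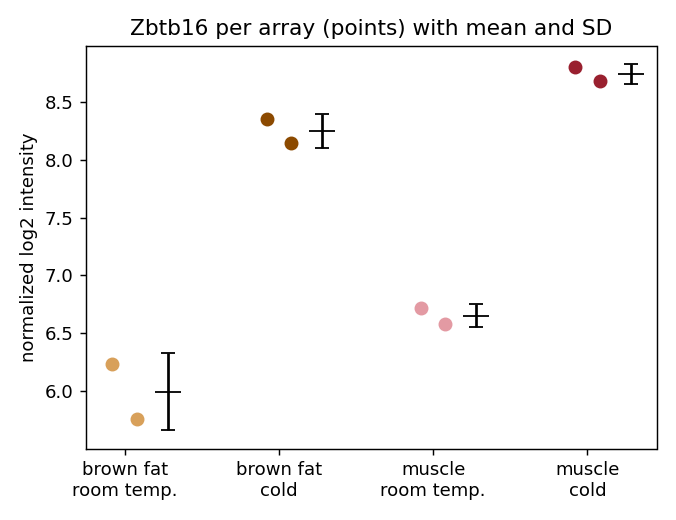
Zbtb16 in each tissue and temperature, as normalized log2 intensity; points are single arrays and the bars beside them the mean and SD of 2 arrays. The 4 cold arrays lie between 8.15 and 8.80 and the 4 room-temperature arrays between 5.76 and 6.72.

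The first comparison asked how brown fat changed within 4 h of cold. The largest rises were in Cyp2b10, a cytochrome P450 (19.4-fold), Lamb3, a laminin chain (16.5-fold), the tight junction gene Cldn1 (11.9-fold) and the cell cycle inhibitor Cdkn1a (9.55-fold). They were followed by Ppargc1a, the coactivator that drives mitochondrial and thermogenic genes (8.45-fold), the stress-induced factor Atf3 (7.80-fold), Dio2, the deiodinase that activates thyroid hormone (7.59-fold), the kinase Plk3 (7.48-fold), the heat shock gene Hsph1 (6.87-fold) and the kinase Ripk4 (6.63-fold). Lep, which encodes leptin, fell at least 25.8-fold to a level not above background, and the lipid droplet gene Pnpla3 (log2 fold change -3.19), the lactate receptor Hcar1 (-3.05), the clock gene Per3 (-2.67) and the adipocyte transcription factor Cebpa (-2.46) were also among the largest falls. The other 5 were Igtp (-3.29), Irgm2 (-3.13), Cd274 (-2.89), Gbp3 (-2.80) and Irgm1 (-2.41), all known as interferon-inducible. Levels of Igtp were 11.80 and 9.55 at room temperature against 7.75 and 7.01 in the cold, and over the alternatives its value ran from -4.42 to -2.16, with the call lost in 3 of 23. Irgm1 read 10.11 and 8.27 against 7.27 and 6.30, ran from -3.32 to -1.49 and lost the call in 8 of 22. The ranges were -4.18 to -2.08 for Irgm2, -3.70 to -2.07 for Cd274 and -3.59 to -2.01 for Gbp3, with calls lost in 3, 3 and 1 of 23. Of the rises, Dio2 lost the call in 5 of 22 alternatives, and Cyp2b10, Atf3 and Plk3 in 4 of 22 each. Standard errors of the 20 genes lay between 0.14 for Per3 and 0.79 for Cyp2b10, and adjusted p between 0.000989 and 0.0314. Other probes of Cyp2b10 and Dio2 gave smaller rises, of 0.56 and 0.96 log2 units against 4.28 and 2.93.

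In all, 835 genes were higher and 821 lower in brown fat in the cold by limma (share higher 50.4%). With median scaling in place of quantile normalization the counts were 58 and 194 (share higher 23%). Counts moved by over 1.5 times without brown fat at room temperature replicate 1 (400 and 383) or 2 (259 and 341), brown fat in the cold replicate 1 (359 and 419), or either muscle replicate at room temperature (536 and 538). There were 204 higher and 218 lower genes past the threshold with all arrays and in each of the 8 leave-outs.

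Genes that answer to cyclic AMP and early stimuli rose as a group in brown fat. Of 21 measured members 10 rose, 1 fell and 10 were not past the threshold (11 higher and 3 lower adjusted over the list alone). Examples are Atf3 (2.96), the phosphodiesterase Pde4d (2.31, SE 0.20) and Maff (1.70, SE 0.15), while Ier3 fell (-1.39, SE 0.17). By camera the adjusted p was 0.00118, and adjusted p = 0.74 with an estimated correlation. Among targets of glucocorticoids and fasting, 10 of 22 rose and 0 fell (10 and 0 adjusted over the list alone), among them Cdkn1a (3.26, SE 0.31), Zbtb16, Fkbp5 (1.69, SE 0.28) and the metallothionein Mt2 (1.11, SE 0.12). Camera gave an adjusted p of 0.000106, and adjusted p = 0.269 with an estimated correlation. Heat shock genes rose in 6 of 8 cases (7 adjusted over the list alone), led by Hsph1 (2.78, SE 0.34), Hsp90aa1 (2.49, SE 0.20), Hspb1 (1.96, SE 0.26) and Bag3 (1.25, SE 0.15). Their camera adjusted p was 0.000106, and adjusted p = 0.269 with an estimated correlation. The estimate was -0.0311, below the preset 0.01, so correlation between genes does not account for the loss of this call. No list was past the threshold in brown fat with an estimated correlation. By fry 7 lists passed in brown fat, among them these groups (adjusted p = 0.0182, 0.00441 and 0.00248, in the order above). The others by fry were white fat markers (0.0115), angiogenesis (0.0154), clock genes (0.0182), and muscle atrophy and autophagy (0.0391).

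Thermogenic genes did not pass as a group by camera, or by fry in 1 direction (adjusted p = 0.53). They passed in fry's mixed form (adjusted p = 0.00952). With all arrays Ppargc1a (3.08, SE 0.26) and Dio2 (2.93, SE 0.59) rose among 16 measured members, 14 were not past the threshold (the counts were 2 and 0 adjusted over the list alone), and the camera adjusted p was 0.399. Without brown fat in the cold replicate 1 and muscle in the cold replicate 2, the list's median was 0.07, against 0.09 with all arrays. Ucp1, the uncoupling protein of brown fat, read between 14.41 and 14.68 on the 4 brown fat arrays, with raw signals of 66.4% to 78.3% of the array's maximum, and its log2 fold change was 0.09 (SE 1.41, adjusted p = 0.978). That error pools all groups, with standard deviations of Ucp1 of 0.02 and 0.19 in brown fat and 3.74 in muscle in the cold. Among 14 transcription factors of brown fat 0 rose and 4 fell (2 and 4 adjusted over the list alone): Cebpa (-2.46), Ebf2 (-1.49, SE 0.23), the thyroid hormone receptor Thra (-0.92, SE 0.13) and Zic1 (-0.74, SE 0.17). The list's median was 0.05 and its mean -0.21, with a camera adjusted p of 0.787.

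Few lipid and glucose genes passed in brown fat. None of 18 fatty acid oxidation genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.61), and the largest values were -0.56 for Hadh (SE 0.20, adjusted p = 0.102) and -0.42 for Ehhadh (SE 0.55, adjusted p = 0.664). Of 20 genes of fatty acid and triglyceride synthesis Pnpla3 fell and 19 were not past the threshold (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.399). Among 19 genes of lipolysis, lipoprotein uptake and lipid droplets, Gpihbp1, which anchors lipoprotein lipase to capillaries, rose (0.47, SE 0.13) and the fatty acid transporter Slc27a1 fell (-0.94, SE 0.21), with 0 and 1 adjusted over the list alone and a camera adjusted p of 0.883. In glucose uptake and glycolysis 3 of 18 genes rose and 0 fell (3 and 0 adjusted over the list alone): the glucose transporter Slc2a1 (1.01, SE 0.21), hexokinase Hk2 (0.49, SE 0.10) and Pgk1 (0.48, SE 0.12). That list's median was 0.02 and its mean -0.15, and its camera adjusted p was 0.815.

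Clock genes moved in both directions. Of 14 measured in brown fat 3 rose, 5 fell and 6 were not past the threshold (3 and 5 adjusted over the list alone, camera adjusted p = 0.315). Per3 (-2.67, SE 0.14) and Dbp (-2.23, SE 0.15) fell, Arntl, the partner of Clock, rose at least 2.39-fold, and Per1 rose by 0.79 (SE 0.10). Of 7 interferon response genes, 4 fell and 3 were not past the threshold (6 lower adjusted over the list alone): Rsad2 (-2.08, SE 0.55), the immunoproteasome subunit Psmb8 (-1.64, SE 0.17), Ifit3 (-1.49, SE 0.30) and Bst2 (-1.36, SE 0.27). The list's adjusted p by camera was 0.000766, and adjusted p = 0.74 with an estimated correlation. The list's median level was 7.95 and 7.46 on the room-temperature arrays of brown fat and 6.68 and 6.40 on the cold ones.

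Genes of vessels and other cell types mostly fell or did not pass. Of 13 angiogenesis genes 4 fell (5 adjusted over the list alone) and 0 rose: Aplnr (-2.06, SE 0.11), Vegfc (at least 2.12-fold lower), Tek (-0.91, SE 0.13) and Nrp1 (-0.87, SE 0.20), with a camera adjusted p of 0.113. Endothelial markers fell in 3 of 12 cases, over all genes and adjusted over the list alone: Emcn (-0.92, SE 0.12), Tek and Ramp2 (-0.53, SE 0.11), with a camera adjusted p of 0.315. Of 8 macrophage markers 2 fell under both adjustments, all genes and adjusted over the list alone: Cd14 (-0.71, SE 0.14) and Fcer1g (-0.68, SE 0.13), camera adjusted p = 0.157. White fat markers fell in 2 of 10 cases (2 adjusted over the list alone), Lep and the imprinted gene Nnat (-1.53, SE 0.27), with a camera adjusted p of 0.297. None of 9 adipocyte markers passed, alone or over all genes (camera adjusted p = 0.787). The largest values were -0.66 for Lipe (adjusted p = 0.374) and -0.52 for Cidec (adjusted p = 0.651). Raw Lipe was 2512.1 and 2240.8 in brown fat at room temperature against 1130.9 and 1707.8 in the cold. Its error pools all groups, and its raw signals in muscle in the cold were 213.4 and 649.3. Among 6 Schwann cell markers Pmp22 rose (0.71, SE 0.18, camera adjusted p = 0.815), and among 12 fibroblast and matrix markers Loxl1 fell (-1.09, SE 0.20, camera adjusted p = 0.455), each with the same count adjusted over the list alone. Muscle atrophy and autophagy genes rose in 4 of 12 cases (4 adjusted over the list alone): Cdkn1a, Gabarapl1 (0.78, SE 0.17), Sqstm1 (0.73, SE 0.12) and Foxo1 (0.50, SE 0.12), camera adjusted p = 0.0676. Without brown fat in the cold replicate 1 and muscle in the cold replicate 2, 1 cold array per tissue was left. Medians there were -0.136 for angiogenesis, -0.31 for macrophage markers and 0.487 for atrophy and autophagy. With all arrays they were -0.17, -0.187 and 0.406. Of the risen or fallen list members named above for brown fat, the call was lost in 12 of 23 alternatives for Gpihbp1 and in 11 of 23 each for Foxo1, Pgk1, Pmp22 and Rsad2, and in at most 8 for the others.

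Muscle transcripts were present on 3 of the 4 brown fat arrays. The skeletal actin Acta1 read 13.85 and 14.24 at room temperature, 6.56 on replicate 1 in the cold and 14.17 on replicate 2, and Ckm read 10.85, 11.30, 5.32 and 11.35. The sarcomere list had a median of -2.27 in the cold, with 0 of 21 members past the threshold over all genes or adjusted over the list alone, such as Acta1 (-3.68, SE 2.03, adjusted p = 0.264) and Tnni2 (-3.63, SE 2.04, adjusted p = 0.273). Its camera adjusted p was 0.012, and adjusted p = 0.944 with an estimated correlation. Without the array of replicate 1, Acta1 was 0.13 and Tnni2 0.21 log2 units higher in the cold (adjusted p = 0.747 and 0.402). Without that array and muscle in the cold replicate 2, the list's median was 0.25. Leaving out that array together with replicate 2 of muscle in the cold gave 585 higher and 677 lower genes in brown fat.

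In quadriceps muscle the same exposure raised Angptl4, an inhibitor of lipoprotein lipase (14.7-fold), Tmem45b (13.6-fold), Arxes2 (11.3-fold), Depp1, a target of forkhead factors (11-fold), and the stress gene Ddit4 (at least 10.3-fold). Slc25a25, a mitochondrial carrier of ATP and magnesium (9.95-fold), Rbp7 (at least 7.37-fold), Irf4 (7.21-fold), the uncoupling protein Ucp3 (5.94-fold) and the forkhead factor Foxo1 (5.39-fold) completed the 10 largest rises. The largest falls included 3 feedback inhibitors of cytokine signalling, Cish (log2 fold change -3.88), Socs3 (-2.82) and Socs2 (-1.97). Cd274 (-3.53), Gbp3 (-2.82) and Irf1 (-1.90), which are interferon-inducible, cardiac actin Actc1 (-2.90), Apol10b (-2.06), the collagen gene Col1a1 (-1.95) and the phosphatase Dusp10 (-1.93) also fell. Standard errors of the 20 genes ran from 0.12 for Foxo1 to 0.74 for Tmem45b, and adjusted p from 0.00121 to 0.0494. Over the alternatives Tmem45b ran from 2.73 to 4.81 and lost the call in 13 of 22, and Arxes2 ran from 2.28 to 4.70 and lost it in 10 of 22. Of the falls, the call was lost in 14 of 22 for Irf1 and Apol10b, 9 of 22 for Actc1, and 8 of 23 for Gbp3 and Socs2; the other 13 genes lost it in at most 4. A second probe of Angptl4 gave 1.16 (SE 0.28, adjusted p = 0.0751), and of 3 other Irf1 probes none was past the threshold in muscle (log2 fold changes -1.31, -0.23 and -0.29).

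In muscle 182 genes were higher and 237 lower in the cold (share higher 43.4%). With median scaling these were 69 and 34 (share higher 67%). Each of these leave-outs moved a count by over 1.5 times: muscle at room temperature replicate 1 (39 higher and 42 lower) or 2 (27 and 19), muscle in the cold replicate 1 (455 and 241) or 2 (100 and 58), and either brown fat replicate at room temperature (92 and 107). There were 25 higher and 13 lower genes past the threshold with all arrays and in each of the 8 leave-outs.

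Brown fat transcripts were present on the muscle arrays in the cold, mainly on replicate 2. Ucp1 read 6.18 and 5.93 in muscle at room temperature, 9.16 on replicate 1 in the cold and 14.45 on replicate 2, and Cidea read 5.81, 5.89, 7.14 and 13.10. Among the 10 largest rises, 3 genes had raw signals of 15% or more of the array's maximum in brown fat at room temperature. Tmem45b read 7.09 and 8.64 at room temperature against 10.59 and 12.67 in the cold, Arxes2 7.11 and 7.54 against 9.61 and 12.03, and Angptl4 6.38 and 6.82 against 9.64 and 11.32. Depp1, in contrast, read 11.42 and 11.07 on the cold muscle arrays against 7.66 and 7.93. Depp1, Rbp7, Irf4, Ucp3 and Foxo1 were also brighter in brown fat than in muscle at room temperature, at 1.18% to 5.77% of the maximum. Of these, Rbp7 (2.2% against 1%) and Irf4 (1.97% against 1.06%) read higher on replicate 2 of muscle in the cold than on replicate 1. Ucp3 (5.76% and 5.7%) and Foxo1 (4.47% and 4.53%) read alike on both. Without the arrays of muscle replicate 2 and brown fat replicate 1 in the cold, 165 genes were higher and 100 lower in muscle, and without genes at least 2-fold higher in brown fat 158 and 319.

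Targets of glucocorticoids and fasting rose together in muscle. Of 22 measured 15 rose, 0 fell and 7 were not past the threshold (20 higher and 1 lower adjusted over the list alone), among them Angptl4 (3.88, SE 0.49), Ddit4 (at least 10.3-fold), Foxo1 (2.43, SE 0.12) and Mt1 (2.35, SE 0.15). The camera adjusted p was 5.44e-22, and adjusted p = 0.0302 with an estimated correlation, the only list in muscle past the threshold in that form. Genes answering to cyclic AMP and early stimuli rose in 8 of 21 cases and fell in 0 (11 and 1 adjusted over the list alone), such as Pde4d (1.98, SE 0.20), the kinase Sik1 (1.60, SE 0.14), Per1 (1.32, SE 0.10) and Nr4a1 (at least 1.85-fold). Their camera adjusted p was 5.83e-07, and adjusted p = 0.294 with an estimated correlation. Muscle atrophy and autophagy genes rose in 4 of 12 cases and fell in 0 (7 and 0 adjusted over the list alone): Foxo1, Cdkn1a (1.60, SE 0.31), Klf15 (0.98, SE 0.13) and Gabarapl1 (0.97, SE 0.17). By camera the adjusted p of this list was 5.83e-07, and adjusted p = 0.287 with an estimated correlation. Foxo1, Cdkn1a and Klf15 are also among the targets of glucocorticoids and fasting, so the results of these lists are not independent. By fry 6 lists passed in muscle, among them glucocorticoid and fasting targets (adjusted p = 0.000322), atrophy and autophagy (0.0104), and cyclic AMP genes (0.0174). The others by fry were Schwann cell markers (0.0159), brown fat transcription factors (0.0311) and angiogenesis (0.0424).

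Several lists of brown fat and adipocyte genes were shifted upward in muscle, where the cold arrays carried the brown fat transcripts given above. Thermogenic genes had a median of 1.16, with Ucp3 (2.57, SE 0.19) risen among 16 (2 adjusted over the list alone); their camera adjusted p was 7.19e-05, and adjusted p = 0.385 with an estimated correlation. Without replicate 2 of muscle in the cold and replicate 1 of brown fat in the cold, the median was 0.06. Brown fat transcription factors rose in 4 of 14 cases and fell in 0 (4 and 0 adjusted over the list alone): Irf4 (2.85, SE 0.29), Cebpb (1.48, SE 0.12), Nr4a1 (at least 1.85-fold) and Nrip1 (0.75, SE 0.15), with a camera adjusted p of 0.000735, and adjusted p = 0.294 with an estimated correlation. Their median went from 0.51 to 0.19 without the pair of arrays. Adipocyte markers had a median of 1.81 with 0 of 9 past the threshold (6 higher adjusted over the list alone), such as Cidec (2.96, SE 0.67, adjusted p = 0.0589) and Adig (2.35, SE 0.52, adjusted p = 0.0567). Their camera adjusted p was 7.51e-06, and adjusted p = 0.385 with an estimated correlation, and without the pair of arrays the median was 0.80. In fatty acid and triglyceride synthesis 2 of 20 genes rose (4 adjusted over the list alone), the carboxylase Acacb (at least 2.09-fold) and Lpin1 (0.81, SE 0.15), with a camera adjusted p of 7.51e-06, and adjusted p = 0.385 with an estimated correlation. The median of that list went from 1.05 to 0.42 without the pair. With the pair left out, 1 cold array per tissue remained. The kept array, muscle in the cold replicate 1, also carried brown fat transcripts. Raw Adipoq there was 3033.8, against 865.5 and 1417.7 at room temperature, so the remaining shifts are not free of them.

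Lipolysis, lipoprotein uptake and lipid droplets had 0 of 19 genes past the threshold (7 higher adjusted over the list alone), such as Cidec and Pck1 (at least 3.96-fold, adjusted p = 0.119). Camera gave an adjusted p of 5.83e-07, and adjusted p = 0.385 with an estimated correlation. The list's median went from 1.23 to 0.32 without the pair of arrays. Fatty acid oxidation likewise had 0 of 18 (3 higher adjusted over the list alone), with Acadl at 0.72 (SE 0.17, adjusted p = 0.0628) and Hadhb at 0.67 (SE 0.15, adjusted p = 0.0552). The list's adjusted p by camera was 0.00141, and adjusted p = 0.385 with an estimated correlation. Its median went from 0.20 to 0.04 without the pair of arrays. In glucose uptake and glycolysis 0 of 18 passed under both adjustments, all genes and adjusted over the list alone, with Pfkl at 1.34 (adjusted p = 0.322) and Pfkp at 1.03 (adjusted p = 0.361). This list's median was -0.01 and its mean 0.07, camera adjusted p = 0.966.

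Clock genes rose in 1 of 14 cases in muscle and fell in 4 (4 and 5 adjusted over the list alone). Per1 rose (1.31, SE 0.10), and Per3 (-1.25, SE 0.14), Dbp (-1.06, SE 0.15) and Bhlhe40 (-1.03, SE 0.12) fell; the median was 0.06 and the mean 0.01 while camera pointed down (adjusted p = 0.986). Of 7 interferon response genes Bst2 (-1.34, SE 0.27) and Psmb8 (-0.94, SE 0.17) fell and 5 were not past the threshold (2 lower adjusted over the list alone). Their camera adjusted p was 0.00169, and adjusted p = 0.447 with an estimated correlation. Among 13 angiogenesis genes 3 fell (4 adjusted over the list alone): Aplnr (-1.17, SE 0.11), Vegfc (-0.82, SE 0.10) and Esm1 (at least 1.58-fold lower), camera adjusted p = 0.09. Heat shock genes had 0 of 8 past the threshold under both adjustments, all genes and adjusted over the list alone, with Hsp90aa1 at least 1.11-fold higher (adjusted p = 0.144) and Hsph1 at 0.39 (adjusted p = 0.576), camera adjusted p = 0.09. Without the pair of arrays the medians were -0.995 for interferon response genes, -0.153 for angiogenesis and 0.371 for heat shock. With all arrays they were -0.94, -0.164 and 0.255.

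Of 6 Schwann cell markers 3 fell in muscle, over all genes and adjusted over the list alone: the glial transcription factor Sox10 (-1.41, SE 0.10) and the myelin genes Mbp (-0.99, SE 0.20) and Mag (at least 1.60-fold lower). Without the pair of arrays the median was -0.66 against -0.56. With all arrays the camera adjusted p was 0.00169, and adjusted p = 0.294 with an estimated correlation. Fibroblast and matrix markers fell in 2 of 12 cases (3 adjusted over the list alone), Col1a1 (-1.95, SE 0.17) and Col6a1 (-0.62, SE 0.11), camera adjusted p = 0.09. Endothelial markers had 0 of 12 past the threshold (2 lower adjusted over the list alone), with Egfl7 at -0.61 (adjusted p = 0.0521) and Cldn5 at 0.57 (adjusted p = 0.402), camera adjusted p = 0.41. Macrophage markers had 0 of 8 under both adjustments, all genes and adjusted over the list alone, with Lyz2 at 0.48 (adjusted p = 0.561) and C1qb at 0.46 (adjusted p = 0.105). Their camera adjusted p was 0.0362, upward, and adjusted p = 0.385 with an estimated correlation. The sarcomere list had 0 of 21 past the threshold in both forms, all genes and adjusted over the list alone, with Myl3 at 1.10 (adjusted p = 0.759) and Myh2 at -0.71 (adjusted p = 0.829), a median of -0.04, a mean of 0.03 and a camera adjusted p of 0.665. Errors of these genes pool all groups, including brown fat arrays that differ in muscle transcripts. Without the pair of arrays the list's median was 0.0007. White fat markers had 0 of 10 (1 higher and 2 lower adjusted over the list alone), with Sncg at 1.96 (adjusted p = 0.071) and Lep at -1.25 (adjusted p = 0.0686); the median was -0.08 and the mean 0.09, camera adjusted p = 0.93.

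Many calls of single list members in muscle depended on the processing or on 1 array. The call was lost in 17 of 22 alternatives for Nrip1, 15 of 22 for Mag, 13 of 22 for Cdkn1a, 13 of 23 for Mbp, 12 of 22 for Bst2, 12 of 23 for Col6a1, 11 of 22 for Lpin1 and 9 of 22 for Gabarapl1. The other list members named above as risen or fallen in muscle lost it in at most 8.

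**Figure D2:**
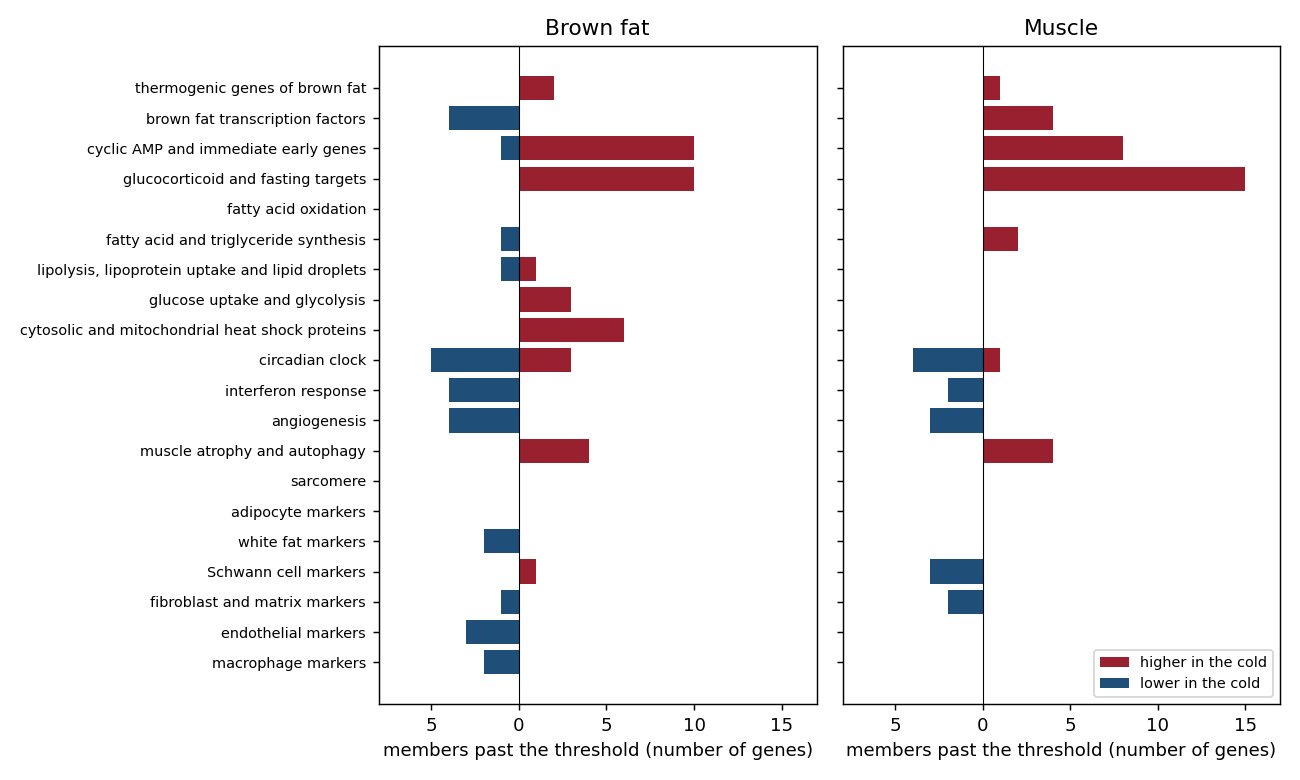
Number of genes per list past the threshold in the cold against room temperature, in brown fat and in muscle; bars to the right count genes higher in the cold and bars to the left genes lower. Targets of glucocorticoids and fasting have the most risen members in muscle, 15 of 22, and heat shock genes rise in brown fat in 6 of 8 cases and in muscle in 0.

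The cold effects overlapped. There were 55 genes higher in both tissues, where independent lists of these sizes would share 15.3 (p = 6.86e-18 by Fisher's exact test), and 87 lower in both, against 19.5 (p = 1.54e-35 by the same exact test). The opposite combinations held 8 and 6 genes, against 19.9 and 15. The log2 fold changes correlated across the 9963 genes at 0.231 by Pearson and by Spearman; genes are not independent replicates. By the smaller change in the pair of tissues, the leading shared genes were Cd274, Gbp3, Cish, Irf1 and Apol10b among those lower in brown fat (-2.89, -2.80, -2.03, -1.93 and at least 3.31-fold lower) and muscle (-3.53, -2.82, -3.88, -1.90 and -2.06). Many alternatives ended some of these calls: Irf1 and Apol10b in muscle as given above, and in brown fat Cish (11 of 23) and Apol10b (10 of 22). Among those higher they were Depp1, Rbp7, Pde4d, Zbtb16 and Fam107a, with 2.44, 2.42, 2.31, 2.26 and 2.17 in brown fat and 3.45, at least 7.37-fold, 1.98, 2.09 and 1.71 in muscle. A second probe of Pde4d gave 0.79 in brown fat and 0.29 in muscle (adjusted p = 0.0144 and 0.318). The counts in both tissues were 10 higher and 5 lower without muscle at room temperature replicate 2, 16 and 8 without replicate 1, 22 and 40 without brown fat at room temperature replicate 2, and 30 and 35 without replicate 1. Without muscle in the cold replicate 1 they were 83 and 60, without replicate 2 they were 34 and 29, and without brown fat in the cold replicate 1 or 2 they were 37 and 51 or 44 and 55. With median scaling they were 11 and 16.

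**Figure D3:**
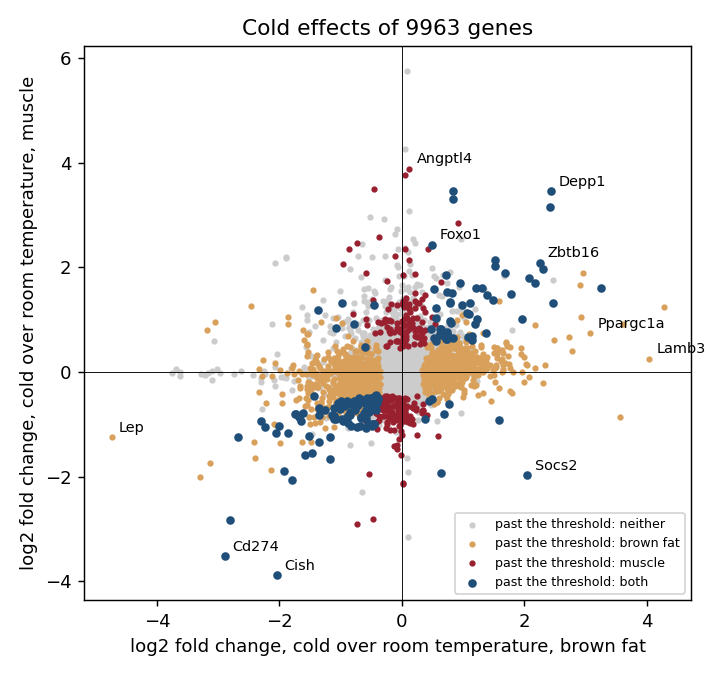
Log2 fold change in the cold of 9963 genes in brown fat (horizontal) against muscle (vertical), coloured by the tissue in which a gene is past the threshold. Zbtb16 lies at 2.26 and 2.09, Cd274 at -2.89 and -3.53, and Socs2 at 2.05 and -1.97.

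The difference of the cold effect between tissues was tested as an interaction. It was positive, with a more upward effect in brown fat, for 207 genes and negative for 213. Cldn1 (difference 4.44, SE 0.60), Socs2 (4.02, SE 0.49), Lamb3 (3.79, SE 0.28), Dusp10 (2.57, SE 0.23) and the cell cycle factor E2f2 (2.51, SE 0.18) led the positive side. Cldn1 read 10.46 and 8.943 on the cold brown fat arrays. Without brown fat in the cold replicate 1 and muscle in the cold replicate 2 its difference was 3.78, below Socs2 (4.245) and Lamb3 (4). Socs2 rose in brown fat (2.05, adjusted p = 0.0106) and fell in muscle, and Dusp10 (0.65, adjusted p = 0.0391) and E2f2 (1.58 against -0.92) did likewise. Hcar1 (-4.01, SE 0.69), Pnpla3 (-3.99, SE 0.48), Angptl4 (-3.76, SE 0.70), Cebpa (-3.72, SE 0.72) and Lep (-3.49, SE 0.42) led the negative side. Hcar1 and Cebpa were not above background in muscle at room temperature, nor Lep in brown fat in the cold, and with the lowest detected signal in their place the differences were -3.59, -3.50 and -3.44. On muscle in the cold replicate 2, which carried brown fat transcripts, Hcar1 read 7.09 against 5.43 on replicate 1 and Cebpa 7.57 against 5.94. The calls were lost in 9 of 21 alternatives for Hcar1, 10 of 21 for Cebpa and 10 of 22 for Angptl4. Without brown fat in the cold replicate 1 and muscle in the cold replicate 2 these 3 differences were -3.24, -2.79 and -3.03. Leaving out brown fat at room temperature replicate 1 gave 7 positive and 18 negative genes, and replicate 2 gave 7 and 9. Without muscle at room temperature replicate 1 there were 13 and 21, without replicate 2 there were 12 and 19, and without brown fat in the cold replicate 1 there were 52 and 58. Leaving out muscle in the cold replicate 1 gave 264 and 553, and replicate 2 gave 108 and 167. With all arrays and in each of the 8 leave-outs, 3 genes were positive and 7 negative. With median scaling there were 16 and 47 (share positive 25.4% against 49.3%).

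Among the lists, 2 were shifted toward brown fat and 8 toward muscle by camera, and 0 with an estimated correlation. By fry 3 lists passed: glucocorticoid and fasting targets (adjusted p = 0.0115), heat shock genes (0.0115) and Schwann cell markers (0.0355). Heat shock genes rose more in brown fat in 3 of 8 cases (6 adjusted over the list alone), Hsph1 (2.39, SE 0.48), Hsp90aa1 (1.87, SE 0.28) and Bag3 (1.08, SE 0.21), with a camera adjusted p of 0.000775, and adjusted p = 0.267 with an estimated correlation. Schwann cell markers had Sox10 past the threshold (1.28, SE 0.15) among 6 (4 adjusted over the list alone), camera adjusted p = 0.00573, and adjusted p = 0.441 with an estimated correlation. Targets of glucocorticoids and fasting rose more in muscle in 7 of 22 cases (2 positive and 9 negative adjusted over the list alone), among them Ddit4 (-2.61, SE 0.29), Mt1 (-2.29, SE 0.22) and Arrdc2 (-2.03, SE 0.16). Their camera adjusted p was 6.12e-05, and adjusted p = 0.267 with an estimated correlation. Brown fat transcription factors differed in 4 of 14 cases (8 adjusted over the list alone), Cebpa, Irf4 (-1.94, SE 0.41), Ebf2 (-1.57, SE 0.33) and Cebpb (-1.09, SE 0.17), camera adjusted p = 0.000459, and adjusted p = 0.412 with an estimated correlation. Leaving out the pair of arrays keeps 1 cold array per tissue. Medians were then 1 for heat shock genes, -0.539 for glucocorticoid and fasting targets and -0.915 for brown fat transcription factors. With all arrays they were 1.01, -0.757 and -0.773. The call on the difference was lost in 16 of 21 alternatives for Irf4, 15 of 22 for Ebf2, 13 of 22 for Aplnr, 13 of 21 for Cd14, 12 of 23 for Hsph1 and Dbp, 12 of 22 for Bag3 and 11 of 23 for Maff; beside these and the 3 genes given above, the list members named here lost it in at most 8. Thermogenic genes had Ppargc1a (2.34, SE 0.36) on the positive and Ucp3 (-2.95, SE 0.27) on the negative side of 16, the same counts adjusted over the list alone, camera adjusted p = 0.242.

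The other lists past the threshold toward muscle include fat or muscle genes, whose levels moved with the brown fat and muscle transcripts given above. They are fatty acid and triglyceride synthesis (2 of 20, 3 adjusted over the list alone: Pnpla3 and Acacb at -1.01; camera adjusted p = 6.12e-05, and adjusted p = 0.602 with an estimated correlation) and lipolysis, lipoprotein uptake and lipid droplets (0 of 19, 3 adjusted over the list alone, Cidec at -3.48, adjusted p = 0.0873; camera adjusted p = 0.000459, and adjusted p = 0.62 with an estimated correlation). Adipocyte markers (0 of 9, 4 adjusted over the list alone, Adipoq at -2.51, adjusted p = 0.0992) had a camera adjusted p of 0.000459, and adjusted p = 0.602 with an estimated correlation. Fatty acid oxidation (0 of 18 in both counts, adjusted over the list alone too, Acadl at -0.87, adjusted p = 0.0853) and sarcomere genes (0 of 21, likewise) had 0.00675 each, and adjusted p = 0.602 and 0.722 with an estimated correlation. Without the pair of arrays the median went from -0.24 to -0.11 for fatty acid oxidation and from -2.36 to 0.10 for sarcomere genes. Medians also shrank from -1.42 to -0.36 for fatty acid and triglyceride synthesis, from -1.15 to -0.41 for lipolysis, and from -1.68 to -0.80 for adipocyte markers. Macrophage markers differed in 1 of 8 cases, Cd14 (-0.995, SE 0.19, 1 adjusted over the list alone), camera adjusted p = 0.00298, and adjusted p = 0.441 with an estimated correlation.

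At room temperature the tissues differed in 6594 of 9963 genes, 3263 higher in brown fat and 3331 higher in muscle. Brown fat was higher in Cidea, a lipid droplet protein (468-fold), Ucp1 (340-fold), the elongase Elovl6 (at least 292-fold), the fatty acid transporter Slc27a2 (at least 140-fold), Kng1 (183-fold), Agpat2 (160-fold), Apoc1 (103-fold), the liver form of glycogen phosphorylase Pygl (82.8-fold), Ltbp2 (76.7-fold) and Poln (at least 60.3-fold). Muscle was higher in Actc1 (130-fold), Nmrk2 (at least 77.9-fold), Trim54 (76.7-fold), the muscle glycogen phosphorylase Pygm (76.2-fold), Mybph (75.3-fold), Ank1 (74.8-fold), Rasd2 (71.9-fold), Smox (71.3-fold), the calcium-binding Casq1 (61.7-fold) and Kcnc4 (60.3-fold). Standard errors of these log2 values ran from 0.16 for Smox to 1.59 for Cidea, and adjusted p from 1.44e-06 to 0.00201. The order and sizes of these folds are uncertain. Raw signals in brown fat at room temperature were 77.3% and 81.2% of the array's maximum for Cidea and 66.4% and 66.8% for Ucp1, and muscle transcripts were present on these brown fat arrays. Casq1 read 8.30 and 8.74 on them against 5.41 on replicate 1 in the cold, and Pygm 7.45 and 7.90 against 5.27. Probes of Ank1 disagreed, since 3 others gave -5.75, -0.76 and -0.33, and another of Kcnc4 gave -3.42 against -5.91. In the cold 3397 genes were higher in brown fat and 2982 in muscle; 2640 and 2568 had the same direction at both temperatures, and 25 and 40 the opposite. With median scaling 1284 and 2162 genes passed at room temperature (share higher in brown fat 37.3% against 49.5%), and 1110 and 1874 in the cold (37.2% against 53.3%).

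**Figure D4:**
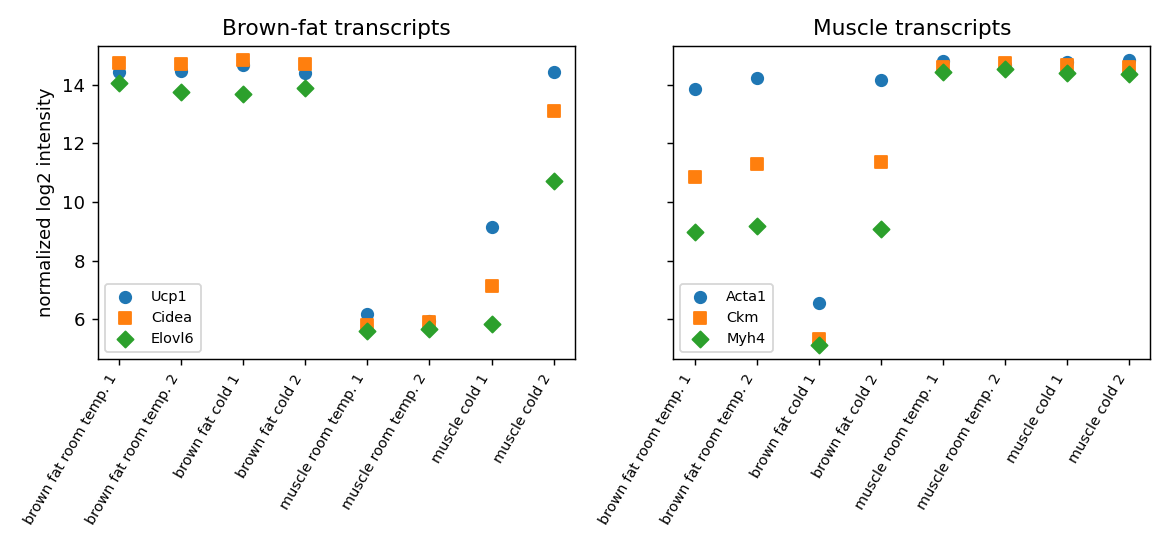
Normalized log2 intensity of 3 brown fat transcripts (left) and 3 muscle transcripts (right) on each of the 8 arrays. Ucp1 reads 14.45 on replicate 2 of muscle in the cold, and Acta1 reads 6.56 on replicate 1 of brown fat in the cold and between 13.85 and 14.24 on the other brown fat arrays.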

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

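The tissue comparison of cold effects was planned, and all tests that weigh explanations below were chosen only after the results were seen. Among the genes named in the comparisons above, list examples included, 34 had a cold effect whose difference between brown fat and muscle was past the threshold in limma's interaction test; each value below is the effect in brown fat minus that in muscle, on the log2 scale, with 2 arrays per group. Of these, 11 were not above background in 1 group: Lep in brown fat in the cold, Arrdc2 in brown fat at room temperature, and Acacb, Cd14, Cebpa, Ddit4, Hcar1, Hsp90aa1, Lamb3, Nnat and Ripk4 in muscle at room temperature, so the sizes of their differences are uncertain.

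Genes with a more upward effect in brown fat, with adjusted p from 0.00635 to 0.045, were Cldn1 (4.44), Socs2 (4.02), Lamb3 (3.79), Dusp10 (2.57), E2f2 (2.51), Hsph1 (2.39), Ppargc1a (2.34), Ripk4 (2.07), Hsp90aa1 (1.87), Col1a1 (1.41), Sox10 (1.28), Maff (1.15) and Bag3 (1.08). Socs2, Dusp10 and E2f2 were past the threshold in opposite directions in the tissues, while Col1a1 and Sox10 fell in muscle and were not past the threshold in brown fat (-0.53 and -0.13, adjusted p = 0.0803 and 0.428).

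Genes with a more upward effect in muscle, or a deeper fall in brown fat, had adjusted p from 0.00635 to 0.0495. Those with a fall in brown fat were Hcar1 (-4.01), Pnpla3 (-3.99), Cebpa (-3.72), Lep (-3.49), Nnat (-2.25), Ebf2 (-1.57), Per3 (-1.43), Dbp (-1.17), Cry2 (-1.16), Cd14 (-0.995) and Aplnr (-0.89), of which Per3, Dbp and Aplnr also fell in muscle. Those with a rise in muscle were Angptl4 (-3.76), Ucp3 (-2.95), Ddit4 (-2.61), Slc25a25 (-2.48), Mt1 (-2.29), Arrdc2 (-2.03), Irf4 (-1.94), Foxo1 (-1.94), Cebpb (-1.09) and Acacb (-1.01), of which Ddit4, Slc25a25 and Foxo1 also rose in brown fat (0.84, 0.84 and 0.50). Raw signals of Mt1 in brown fat were 76.5% to 83.8% of the array's maximum.

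The array of muscle in the cold replicate 2 carried brown fat transcripts, with Ucp1 at 14.45 against 6.18 and 5.93 at room temperature. All 57 genes at least 32-fold higher in brown fat at room temperature (100%) were above both room-temperature muscle arrays there, by a median of 13% of the brown fat signal, and across them the excess correlated with the level in brown fat in the cold (Pearson 0.87; 0.857 with the room-temperature level). A rise with cold in both muscle samples alike is argued against by a median rise of 0.304 on replicate 1 and 2.93 on replicate 2, and a brown fat sample labelled as muscle by muscle genes only -0.195 from the other muscle arrays, where the tissues differ by -5.34. The share was not the same for all genes, from 4.35% for Kng1 to 93% for Ucp1 (quartiles 8.71% and 24.2%), and its log2 correlated with the brown fat level at only 0.225. The highest shares have limits. Raw Ucp1 was 70.8% of the array's maximum there and 66.4% to 78.3% in brown fat, near the top of the scale. Arxes2 (83.5%), Tmem45b (64.6%) and Angptl4 (40.6%) also rose on replicate 1, to raw signals of 857.2, 1642.6 and 874.4 from at most 242.6, 449.9 and 170.4 at room temperature. Brown fat RNA in that sample is a candidate explanation, but 1 source in 1 ratio does not account for the whole spread. The reason for the spread, how the RNA came there, and a response of that sample alone remain open. On that array the white fat marker Sncg had a raw signal of 3157.3, above every brown fat array (663.3 to 1447.4). RNA like that of these brown fat samples does not alone account for it. Lep, another such marker, was lower there (137.5) than on the room-temperature muscle arrays (194.9 and 327.3). Another source of fat RNA was not tested.

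Muscle transcripts stood on 3 of 4 brown fat arrays and were near the floor on replicate 1 in the cold. Of 67 genes at least 32-fold higher in muscle at room temperature, 63 (94%) were lowest on that array. The excess on the others had a median of 1.44% of the muscle signal and correlated with the level in muscle (Pearson 0.785). Neither value tests for muscle RNA, since the 32-fold limit itself keeps the excess low and ties it to the muscle level. Raw Pgam2 showed a larger share, with 2661.3 and 2827.3 in brown fat at room temperature against 24380.8 and 24599 in muscle. A fall with cold in both samples is argued against by a median change of 0.285 on replicate 2 against -1.06 on replicate 1. Some muscle RNA in the other 3 samples may account for this; whether it was taken with the tissue was not tested.

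The interferon response list had medians of -1.46 in brown fat and -0.94 in muscle, with 4 and 2 of 7 genes fallen. Fewer macrophages are argued against by macrophage marker medians of -0.187 (error 0.118) and 0.287 (error 0.0731). This holds less in brown fat, where 2 of 8 such markers fell and their median was -0.31 without the pair of arrays. A high level on 1 room-temperature array does not account for all of it, with medians of -1.07 and -0.602 without the higher array of each tissue, nor does quantile normalization, with -1.39 and -0.996 relative to all genes under median scaling. A response to the exposure is a hypothesis that these data may hold, but cold and the removal of food and bedding cannot be separated here. Other immune cells were hardly measured, with 3 lymphocyte markers tested. Their medians were -0.596 in brown fat and -0.273 in muscle, with 0 of 3 positive in each, so fewer lymphocytes were not ruled out.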

How the results depend on the processing

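The alternatives were planned, except 2 that were chosen after the results were seen. These left out the 2 arrays of brown fat in the cold replicate 1 and muscle in the cold replicate 2, or genes higher in the other tissue. The muscle array of that pair carried brown fat transcripts. The brown fat array of the pair, in contrast, lacked the muscle transcripts that the other brown fat arrays carried. Leaving out the pair therefore keeps the brown fat arrays with muscle transcripts. It also keeps muscle in the cold replicate 1, on which Ucp1 read 9.16 against 6.18 and 5.93 at room temperature. With 1 array left in each cold group, the spread comes from the room-temperature arrays alone. Zbtb16 kept its direction and call for both cold effects wherever it was tested. For the counts, list tests, overlaps and Zbtb16, no background correction, an offset of 50, normalization within each tissue, all probes, and a variance trend with robust moderation moved no count by over 1.5 times and ended no call of Zbtb16 where it was tested, while 6 lists in place of 5 passed in brown fat without background correction and 12 in place of 13 in muscle with the offset. Of 83 results past the threshold of genes named by size of change, overlap or the series title, list examples aside, 23 lost the call with the variance trend, 14 without a filter, 13 with the authors' values, 11 with the compared groups alone and 8 without the 2 arrays. Leaving out 1 array ended 22 calls without muscle at room temperature replicate 2, 18 without its replicate 1 or either brown fat replicate at room temperature, 16 without either brown fat replicate in the cold, and 6 and 9 without muscle in the cold replicate 1 and 2. A block for chip or scan was not run, since neither is given. The causes of the changes below were not tested.

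With median scaling the median of all genes was -0.107 for the cold effect in brown fat, -0.198 in muscle, 0.07 for the difference, -0.238 for the tissues at room temperature and -0.121 in the cold. Higher and lower genes numbered 58 and 194 in brown fat, 69 and 34 in muscle, 16 and 47 for the difference, 1284 and 2162 for the tissues at room temperature and 1110 and 1874 in the cold; 9 lists passed in brown fat, and 11 and 16 genes overlapped. Zbtb16 was -0.99 between tissues at room temperature (adjusted p = 0.0535) and -0.83 in the cold (0.125).

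With an estimated correlation 0 lists passed in brown fat, 1 in muscle and 0 for the difference, against 5, 13 and 10. The authors' values gave 113 and 122 in muscle, 88 and 114 for the difference, 42 lower in both, and Zbtb16 -0.49 between tissues in the cold (0.102); without a filter this was -0.49 (0.0662), and with a minimum fold of 1.5 also -0.49, not past it. That minimum gave 543 higher in brown fat and 54 lower in both. Detection on all arrays gave 2 lists in brown fat and 8 in muscle, 2099 and 2077 genes between tissues at room temperature and 1844 lower in the cold. Fitting the compared groups alone gave 470 and 515 in brown fat, 65 and 64 in muscle, and 25 and 23 in both. Deviations of arrays with the same replicate number correlated between -0.125 and 0.181. With 2 arrays per group, and cold arrays that differ in signal of the other tissue, this cannot show whether the numbers mark pairs. As a block the numbers gave 120 and 121 in muscle, 81 and 105 for the difference and 48 lower in both. The descriptions' numbers gave 124 positive differences. Without the 2 arrays there were 8 lists in brown fat, 100 lower in muscle, 92 positive differences, 45 lower in both, and Zbtb16 -0.65 between tissues in the cold (0.0572). Without genes higher in the other tissue 6 lists passed in muscle and 2 for the difference.

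In leave-outs a lone array is assumed to vary like the other groups. Genes numbered 259 to 864 higher and 341 to 904 lower in brown fat, 27 to 455 and 19 to 241 in muscle, 7 to 264 and 9 to 553 for the difference, and 10 to 83 and 5 to 60 in both tissues. Zbtb16 ran from -0.89 to -0.42 between tissues at room temperature and from -0.59 to -0.39 in the cold, and its difference in cold effect ran from -0.068, without brown fat at room temperature replicate 2, to 0.40. Turns of other results came with brown fat in the cold replicate 1 left out, against replicate 2 left out: in brown fat Acta1 was 0.13 against -7.49 and Tnni2 0.21 against -7.46, and the differences were 0.29 against -5.56 for Pgam2, 0.27 against -4.79 for Eno3, 0.074 against -7.54 for Acta1 and 0.20 against -7.46 for Tnni2. Without the 2 arrays these 6 were 0.13, 0.21, 0.34, 0.28, 0.10 and 0.20. In muscle Myl3 ran from -1.02 without muscle in the cold replicate 1 to 3.21 without replicate 2, and Myh2 from -1.90 without replicate 1 to 0.47 without replicate 2 and without the 2 arrays.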

Other observations

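Beyond the groups above, the endoplasmic reticulum stress list moved in both directions in brown fat. Of 14 genes Atf4 rose (1.13, SE 0.16), and Xbp1 (-1.46, SE 0.15), Herpud1 (-0.75, SE 0.18) and Pdia4 (-0.58, SE 0.11) fell (2 higher and 3 lower adjusted over the list alone), with a camera adjusted p of 0.939. In muscle 0 of 14 passed, and the camera adjusted p was 0.00981, upward, and adjusted p = 0.294 with an estimated correlation. The effect on Xbp1 differed between tissues by -1.63 (SE 0.21, adjusted p = 0.0179). In the cytokine and inflammation list of 9 genes Nfkbia rose in brown fat (0.73, SE 0.16, camera adjusted p = 0.939) and Socs3 fell in muscle (-2.82, SE 0.37, camera adjusted p = 0.46). Of 3 lymphocyte markers Cd74 fell in brown fat (-0.88, SE 0.23, camera adjusted p = 0.113), and 0 passed in muscle (camera adjusted p = 0.556).

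Few genes of the mitochondrial lists passed: of 22 respiratory chain genes 0 passed in either tissue (camera adjusted p = 0.399 in brown fat and 0.702 in muscle), of 15 citric acid cycle genes 0 (0.815 and 0.47), and of 15 genes of branched-chain amino acid breakdown Ivd fell in brown fat (-0.40, SE 0.10; 0.585 and 0.47). Of 14 cholesterol genes 0 passed in either tissue (0.815 and 0.104), while 4 were higher in brown fat without brown fat in the cold replicate 1 and muscle in the cold replicate 2 (camera adjusted p = 0.265). Among 11 calcium cycling genes the phospholamban gene Pln fell in muscle (-0.72, SE 0.13), and the camera adjusted p was 0.222 in brown fat and 0.647 in muscle, with 2 higher in brown fat without that pair. Of 5 cell cycle genes Mcm2 fell in brown fat (at least 1.22-fold lower; 0.399 and 0.966). Neither 3 neutrophil markers (0.984 and 0.93) nor 4 red blood cell markers (0.963 and 0.09) had a member past the threshold in either tissue. Without the pair the red blood cell list had a median of 0.695 in muscle, against 0.465 with all arrays.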
